A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

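Histone H3 acetylated at lysine 9 (H3K9ac) was mapped in asynchronous fission yeast (Schizosaccharomyces pombe) cells by chromatin immunoprecipitation followed by hybridisation to tiling microarrays (ChIP-chip). Cells were grown at 30 C and crosslinked at 18 C for 30 minutes, per the labels. The 6 arrays fell into 3 groups of 2 replicates by their labels: wild type, a strain with the alp13 gene deleted, and the pst1-1 mutant. On every array the immunoprecipitated DNA carried Cy5 and the whole cell extract DNA carried Cy3, so dye and sample type were not separated. The custom Agilent array held 41551 probes of 60 bases, spaced about every 300 bp along the genome, and 2256 control spots.

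Per the file headers, Agilent Feature Extraction 8.5.1.1 made the scanner files. The deposited processed signals are in units of intensity, normalised between the dyes within each array with a LOWESS setting, and per the file headers they had no background subtracted. The deposited log ratios are log10 values of processed Cy5 over processed Cy3. The deposited table of the whole series holds log2 values. Each of its columns equalled the log2 ratio of the median pixel signals plus 1 constant per array, to within 0.00505, and the constants, whose origin is not stated, ranged from -0.18 to 0.13.

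For each probe, the log2 ratio of processed Cy5 to processed Cy3 signal was centred on the median of its array. Values are therefore relative to the genome of the same array, and a change shared by all probes would not appear. The 2754 probes (6.63%) marked by the scanner software as a non-uniformity or population outlier on any array were left out, and 38797 probes were used. The sources used here do not give the genome build behind the probe names. Probes were placed by exact matches of their sequence on the ASM294v3 assembly of the reference genome with its PomBase annotation. Of all probes, 40396 matched at 1 place, 1053 at several places and 102 at none. A gene's upstream value was the mean over probes with midpoints within 500 bp upstream of its start codon and outside any other coding span (at least 1 probe, 4631 genes). A gene's coding value was the mean over probes between start and stop codon (at least 2 probes, 4599 genes). Neighbouring genes that share a divergent upstream region share probes. For the profile along genes, coding spans of at least 900 bp were divided into equal parts, and the 500 bp downstream of the stop codon were added.

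Tests used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). The limma model held the 3 groups in a single fit of all 6 arrays, with 3 residual degrees of freedom before moderation, empirical Bayes moderation without a trend, 2-sided tests and Benjamini-Hochberg adjustment within each comparison, called at 0.05. Adjusted p-values below are from this fit unless another test is named. With 2 arrays against 2, the exact permutation test of group means cannot give a p below 0.333, and the number of arrays limits the precision of every value. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these arrays only. Each group had 1 array on each of 2 scanning days, and replicate number and scanning day divide the arrays in the same way. Deviations of the replicates from their group means were correlated over probes between groups (0.636 for wild type and alp13 deletion, 0.450 for wild type and pst1-1, 0.385 for the mutants), so the replicate numbers pair the samples. A fit with the replicate as a block (2 residual degrees of freedom) was run beside the fit without it, and its counts are given where they differ by more than 1.5 times. Each slide held 1 array, so a slide block could not be fitted.

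Before the data were examined, 18 gene lists were fixed: cytosolic ribosomal proteins, glycolysis, histones, mating, meiosis and sporulation, core stress response, chaperones, iron uptake, phosphate and thiamine repressed genes, sugar transport and glucose-repressed genes, cell surface adhesins, proteasome, deacetylase complexes, S phase genes, Tf2 retrotransposons, wtf genes, subtelomeric genes (within 100 kb of the ends of chromosomes I and II) and genes within 20 kb of the centromeres. Lists with at least 5 measured members were tested with limma camera at a preset correlation between genes of 0.01, and again with the correlation estimated. A camera call compares a list with the other genes. The limma fry test, which asks whether a list's own genes move on balance in a single direction, was run beside it. Chromosome regions were tested with limma over the mean of their probes. The sets of RNA genes were not limited to the nuclear chromosomes and can hold probes of mitochondrial DNA. The named genes followed a rule also fixed then: for each comparison and each of upstream and coding values, among genes with a symbol, an adjusted p below 0.05 and arrays of the groups that do not overlap, the 8 largest increases and the 4 largest decreases; up to 4 members of each list by smallest p; and always clr6, pst1, pst2, alp13 and prw1. A gene outside the rule is named as chosen after its values were seen. The pipeline was tested on simulated data with 100 regions shifted by 0.5 and 100 by 1 on the log2 scale: for coding regions it recovered 85 and 99 with 10 false calls, and for upstream regions 48 and 100 with 14 false calls.

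Alternatives fixed before the data were examined were background-corrected signals (normexp, offset 50), loess within arrays, scaling arrays to the same spread, the series table's values, keeping the marked probes, only probes well above background in the extract, probes with a single place, a 300 bp upstream window, upstream probes of a single gene only, at least 4 probes per coding region, a trended robust prior, the replicate block, only the 4 arrays of both groups compared, and leaving out each array in turn. Added after the data were seen were normexp together with the replicate block and leaving out probes with low extract signal. Median Cy3 signal per array was 1618 and 925 in wild type, 1449 and 808 in the alp13 deletion and 1564 and 868 in pst1-1 (replicates 1 and 2). The local background made up 18.5% to 39.0% of the median Cy3 signal, with the larger shares on the arrays of the later scanning day.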

Results

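H3K9 acetylation was measured in fission yeast as the log2 ratio of precipitated to extract DNA on 6 tiling arrays. Of these, 2 were of wild type, 2 of an alp13 deletion and 2 of pst1-1. Alp13 and Pst1 are subunits of complexes built around the histone deacetylase Clr6. Pst1 belongs to complex I and Alp13 to complex II. The design asks where acetylation of H3K9 changes when either complex is impaired. A log2 ratio of 0 marks the median probe of an array. Across probes, the replicates correlated at 0.882 in wild type, 0.876 in the alp13 deletion and 0.935 in pst1-1. Wild type and pst1-1 arrays correlated at 0.836 to 0.905, and wild type and alp13 deletion arrays at 0.428 to 0.657.

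In wild type, H3K9ac was highest upstream of genes and declined along the coding span. The mean over genes was 0.26 ± 0.12 (SD, n = 2) in the 500 bp upstream of the start codon, and -0.00 ± 0.10 in the 500 bp downstream. With the coding span divided into 3 equal parts, it was 0.10 ± 0.01 in the first, -0.12 ± 0.09 in the middle and -0.13 ± 0.05 in the last part. Upstream exceeded coding values by 0.26 ± 0.15 over 4159 genes with both. Centromeric repeats, which carry heterochromatin, lay at -1.97 ± 0.13 (274 probes), tRNA genes at -1.08 ± 0.08 (54 probes), the outermost 100 kb of chromosomes I and II at -0.40 ± 0.01 (1098 probes) and the mating-type region at -0.38 ± 0.00 (68 probes). These are the mating-type probes that match the reference. Those named for the region without a match lay lower, at -1.56 ± 0.10 (33 probes). Mitochondrial DNA, which has no histones, gave the background of the assay at -3.09 ± 0.13 (47 probes). The tRNA set was not limited to nuclear genes and can hold some of these probes.

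**Figure D1:**
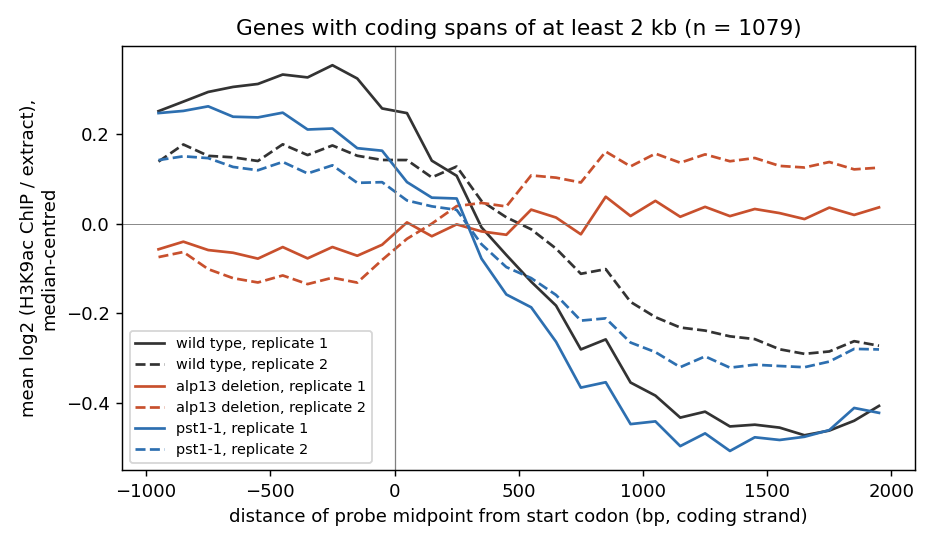
Mean log2 ratio of H3K9ac ChIP to extract in 100 bp steps around the start codon, for 1079 genes with coding spans of at least 2 kb, with 1 line per array. At 250 bp upstream the wild-type arrays stand at 0.35 and 0.18 and the alp13 deletion arrays at -0.05 and -0.12; at 1550 bp into the coding span they stand at -0.46 and -0.28 against 0.02 and 0.13.

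In the alp13 deletion H3K9ac fell upstream of genes and rose in the middle and last parts of their coding spans, relative to the array median. Mitochondrial DNA, the background of the assay, moved by -0.58 relative to that median, further than the upstream mean did. Values were also not corrected for histone density. The direction of the upstream change on an absolute scale is therefore not determined. Of 4631 upstream regions, 1950 fell and 16 rose. Of 4599 coding regions, 818 rose and 544 fell. The upstream mean was -0.11 ± 0.03 (n = 2) in the deletion, a difference from wild type of -0.37, while the middle and last parts of the coding span were higher by 0.19 each (0.07 ± 0.07 and 0.06 ± 0.03). The first part was lower (-0.08). The mean of whole coding spans changed by 0.02 (exact permutation p = 0.667). The median of all coding regions, 0.02, turned to -0.03 with background correction and was also below 0 with the series table. Coding probes were 24673 of the 38797 used, so centring on the array median holds these averages near 0. They cannot show whether coding spans gained as a set. The coding minus upstream difference rose by 0.38 on average and was positive in 91.0% of 4159 genes. By limma per gene, 1485 rose and 8 fell. The 500 bp downstream differed by -0.10 (-0.13 and -0.07 on the scanning days; exact permutation p = 0.667 without pairing).

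The coding minus upstream difference was 0.44 on the earlier and 0.33 on the later scanning day. Its exact permutation p of 0.333 (n = 2 and 2, 2-sided) is the smallest that 2 arrays against 2 can give. The same p was obtained for the upstream mean and the first, middle and last parts of the coding span. Upstream regions whose arrays did not overlap between the groups made up 77.7%, and coding regions 68.8%, against 33.3% for exchangeable arrays. The replicate numbers pair the samples, so the share by chance may differ from that value. With the replicate as a block 45 upstream regions rose and 2851 fell, 1374 coding regions rose and 1083 fell, and 2495 genes rose and 30 fell in the coding minus upstream difference. The counts moved when single arrays were left out. Changed upstream regions numbered 693 without wild type replicate 1, 737 without alp13 deletion replicate 2 and 1267 without alp13 deletion replicate 1, but 2308 without wild type replicate 2. Changed coding regions numbered 223, 505 and 687 in the same order. Genes changed in the coding minus upstream difference numbered 296 without wild type replicate 1, 293 without alp13 deletion replicate 2 and 2144 without wild type replicate 2. With background-corrected signals the median upstream difference of all genes was -0.74 in place of -0.37, with loess -0.61 and with the series table's values -0.50. The shares of changed coding regions that rose were 49.9% with background correction and 50.6% with the series table, against 60.1%. The share was 82.6% with at least 4 probes per coding region, which leaves out short genes, and 46.2% without wild type replicate 1.

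**Figure D2:**
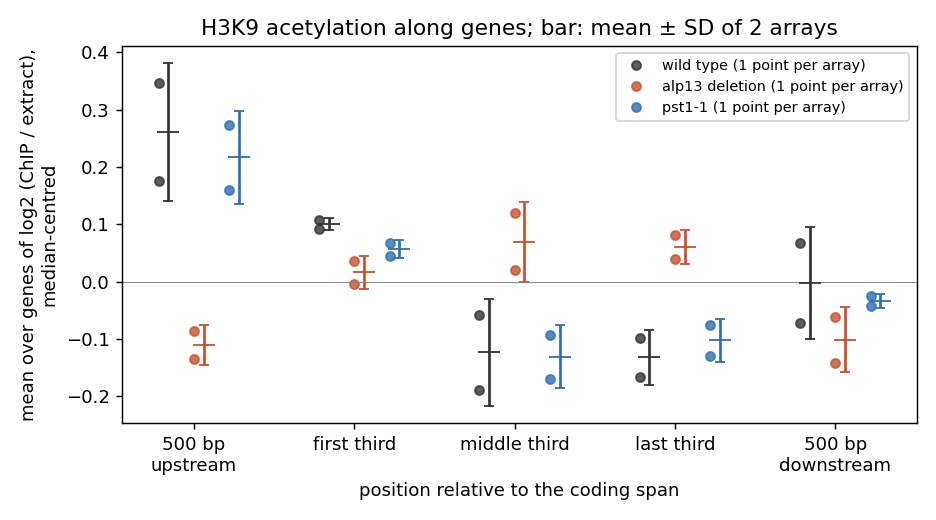
Mean over genes of the median-centred log2 ratio of ChIP to extract at 5 positions relative to the coding span; points are arrays and bars are the mean ± SD of 2 arrays. The alp13 deletion lies below wild type upstream (-0.11 against 0.26) and above it in the last part of the coding span (0.06 against -0.13), and pst1-1 lies near wild type at both (0.22 and -0.10).

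By probe, 4525 rose and 5957 fell of 38797 in the alp13 deletion. Inside coding spans 4287 of 24673 probes rose and 1315 fell, in upstream sequence 19 of 6179 rose and 1994 fell, and in other noncoding sequence 218 of 7854 rose and 2629 fell. With the replicate block 8382 probes rose and 10954 fell. Without alp13 deletion replicate 2 the number of changed probes was 1237, without wild type replicate 1 it was 1881, and without alp13 deletion replicate 1 it was 2963.

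Among coding regions, the largest increases in the alp13 deletion were, in order, at the flocculin genes gsf2 and pfl3, at adg2, a cell wall glycoprotein, and at spc7, a kinetochore protein. They were followed by pop2, an F-box protein of a ubiquitin ligase, fml1, a DNA helicase, utp13, a factor of ribosomal RNA processing, and pfl5, a flocculin. The coding value of gsf2 (chromosome III, 959281 to 963972, ASM294v3) rose by 1.14 ± 0.30 (SE) to 0.14 ± 0.54 (n = 2), with a limma adjusted p of 0.0269. For this gene 7 probes match more than 1 place. Values for spc7 (III, 786520 to 790614) rose from -0.63 ± 0.07 to 0.34 ± 0.09, by 0.97 ± 0.10 (adjusted p = 0.00604). The remaining increases were 1.04 for pfl3, 1.02 for adg2, 0.94 for pop2, 0.90 for fml1, and 0.88 for utp13 and pfl5. Probes of pfl3 and pfl5 also match several places. The largest decreases in coding regions were -0.96 at mug155, a gene upregulated in meiosis, -0.95 at isp7, a gene induced in sexual development, -0.93 at sro1 and -0.91 at snx3, a sorting nexin. The increases of gsf2, adg2 and pfl5 did not pass without wild type replicate 1 (0.91, 0.79 and 0.62) or without alp13 deletion replicate 2 (0.77, 0.61 and 0.54). That of pfl3 did not pass without wild type replicate 1 (0.81) and was 0.69 without alp13 deletion replicate 2.

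Upstream regions fell most at plb2, a phospholipase gene (I, 3034882 to 3036816), from 0.33 ± 0.36 to -1.08 ± 0.01 (n = 2), a difference of -1.42 ± 0.20 with a limma adjusted p of 2.18e-04. Values at isp7 fell by 1.34, at pos5, a kinase of NADH, by 1.30, and at ppk9, a protein kinase, by 1.26. Of the 16 upstream regions that rose, the largest increase was at mug125 (I, 1086376 to 1087233), from -1.05 ± 0.02 to -0.33 ± 0.09, by 0.73 ± 0.16 (adjusted p = 0.00286), followed by gas4, a glucan synthesis enzyme of the spore wall (0.68), mfm3, a pheromone precursor (0.63), and gep4, a mitochondrial lipid phosphatase (0.61). Smaller increases were at dni2, a cell fusion protein (0.52), mug27, a meiotic protein kinase (0.50), and pat1, the kinase that holds back meiosis (0.48). At cao1, a copper amine oxidase, the upstream value rose by 0.48, while the extract DNA of its coding region in wild type was close to the local background (1.12 and 1.05 times). Most of these upstream values rest on 1 probe, and 6 of the 8 named increases did not pass when some single array was left out. The value of gas4 was 0.45 without wild type replicate 1 and that of gep4 0.48 without alp13 deletion replicate 1. Without alp13 deletion replicate 1 the other values were 0.57 for dni2, 0.31 for mug27, 0.20 for pat1 and 0.50 for cao1. Without alp13 deletion replicate 2 the value of pat1 was 0.76, which passed. With the series table the upstream change of cao1 was 0.06 and did not pass. Without wild type replicate 1 those of dni2, pat1 and cao1 were 0.43, 0.52 and 0.46. Those of mug27 and pat1 were 0.32 and 0.43 without wild type replicate 2, and those of dni2 and cao1 were 0.47 and 0.45 without alp13 deletion replicate 2.

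Of the genes for Clr6 complex subunits, pst1, clr6 and pst2 had higher coding values in the alp13 deletion, by 0.41, 0.37 and 0.34 (limma adjusted p of 0.0363, 0.0182 and 0.0176). None of these calls held without wild type replicate 1 (0.31, 0.43 and 0.33) or without alp13 deletion replicate 1 (0.45, 0.36 and 0.33) or 2 (0.36, 0.38 and 0.36), and that of clr6 not without wild type replicate 2 (0.31) either. The difference at prw1 was 0.20 (adjusted p = 0.0993, and 0.0273 with the replicate block). Upstream of pst1 the value fell by 0.66 (-0.52, not passing, without alp13 deletion replicate 2), and upstream of prw1, pst2 and clr6 the differences were -0.40, -0.21 and -0.11 (adjusted p of 0.0504, 0.259 and 0.605; 0.00589 for prw1 with the replicate block). At alp13 itself, the deleted gene, the extract signal over the array median was 0.14 ± 0.02 in wild type, 0.04 ± 0.07 in pst1-1 and -1.76 ± 0.58 in the deletion (log2, n = 2), so its coding ratio in the deletion (0.03, a difference of -0.49 from wild type) is one of background signals. The upstream difference was -0.77, and the coding call did not hold without wild type replicate 1 (-0.44).

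Tf2 retrotransposons fell upstream and rose over the coding span. Upstream, all 10 measured copies fell (10 adjusted over the list alone; median -0.97), for example Tf2-2 and Tf2-4 by 1.09 each. Over coding sequence all 13 rose (13 adjusted over the list alone; median 0.78, with 0.45 on the earlier and 1.11 on the later scanning day). For Tf2-2, Tf2-4 and Tf2-9 the coding value of 0.80 did not pass without wild type replicate 1 (0.76), and was 0.44 without alp13 deletion replicate 2. Probes of Tf2 match several copies, so the copies are not independent. Subtelomeric genes fell in both parts: 51 of 110 upstream (57 adjusted over the list alone; median -0.43) and 41 of 115 in coding regions (46; median -0.29), with none rising in either. These medians moved with the scaling, to -0.80 upstream and -0.63 in coding regions with background correction, and to -0.58 in coding regions with arrays scaled to the same spread. Examples are gdt1 upstream (-0.85), yhb1, a flavohaemoglobin, upstream (-0.68), and the coding regions of ecl3 (-0.75) and of the fluoride exporters fex1 and fex2 (-0.55 each). Ribosomal protein coding regions lay lower than other genes by camera at the preset correlation, but not with an estimated one. Their median was -0.24, against -0.20 in all genes under 1000 bp. Of 54, 48 did not pass and 6 fell (3 adjusted over the list alone), among them rpl1801 (-0.55) and rps901 (-0.50). Some of these examples did not pass without single arrays: yhb1 (-0.52) and rpl1801 (-0.47) without alp13 deletion replicate 1, rpl1801 (-0.57), fex1 and fex2 (-0.42 each) without wild type replicate 1, and fex1 and fex2 (-0.44 each) without alp13 deletion replicate 2.

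The camera adjusted p at the preset correlation was 5.48e-07 for Tf2 and 0.0295 for subtelomeric genes upstream, and 4.71e-05, 4.79e-16 and 1.34e-06 for Tf2, subtelomeric and ribosomal protein genes in coding regions. None of these calls held with an estimated correlation. It gave an adjusted p of 0.706 for each upstream list and of 0.933 for each coding list, and both figures also apply to the calls in the next sentences. Upstream, 3 lists lay above the other genes, whose median was -0.37. For meiosis and sporulation genes (median -0.26, camera adjusted p = 0.00143), 33 of 119 fell and 2 rose (28 and 1 adjusted over the list alone), with mug105 at -1.24 and mug35 at -1.03. For S phase genes (median -0.11, adjusted p = 0.0209), 1 of 13 fell (1 adjusted over the list alone), namely suc22, a ribonucleotide reductase subunit (-0.54). For iron uptake genes (median -0.12, adjusted p = 0.0295), 1 of 10 fell (0 adjusted over the list alone), namely sib2 (-0.40), an enzyme of siderophore synthesis. The calls of suc22 (-0.49, -0.56 and -0.51) and sib2 (-0.36, -0.43 and -0.37) did not hold without wild type replicate 1 or either alp13 deletion array, nor that of sib2 without wild type replicate 2 (-0.44).

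The remaining upstream lists did not differ from other genes by camera (adjusted p of 0.170 to 0.982, and of 0.706 to 0.993 with an estimated correlation), and their members mostly fell or did not pass. Ribosomal protein genes had 46 of 127 lower (37 adjusted over the list alone), with rpl8 at -0.94, and proteasome genes 13 of 30 (14), with pre6 at -1.08. Genes near the centromeres had 16 of 44 (16), with ngg1 at -0.81 (-0.59, not passing, without alp13 deletion replicate 2), and glycolysis genes 6 of 15 (5), with pdc101, a pyruvate decarboxylase, at -0.84. Deacetylase complex genes had 5 of 14 lower (6), core stress genes 4 of 15 (4), and wtf genes 4 of 15 (4). Chaperones had 4 of 11 (4) with mas5 at -0.81, histone genes 4 of 10 (4) with the shared region of hht1 and hhf1 at -0.70 (-0.43, not passing, without wild type replicate 1), sugar genes 3 of 12 (2), and adhesins 3 of 11 (2). Phosphate and thiamine genes had 6 of 9 lower and 1 higher (6 and 1), and mating genes 3 of 14 lower and 1 higher (3 and 1). By fry, subtelomeric genes moved on balance to lower upstream values (adjusted p = 0.0140).

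Coding regions of the other lists were not called by camera (adjusted p of 0.217 to 0.889, and 0.933 with an estimated correlation). S phase genes had 6 of 14 higher (6 adjusted over the list alone), with pol1, the polymerase alpha catalytic subunit, at 0.75 and cdc10 at 0.52 (0.45, not passing, without wild type replicate 1). Adhesins had 4 of 11 higher and 1 lower (6 and 2; median 0.53), genes near the centromeres 10 of 41 higher and 3 lower (10 and 8), with prm1 at 0.81 and meu27 at 0.82, and deacetylase complex genes 4 of 15 higher and 1 lower (4 and 1), the lower one being alp13. By fry the last list moved on balance to higher values (adjusted p = 0.00276). Meiosis genes had 23 of 112 higher and 17 lower (23 and 18), mating genes 3 of 13 and 1 (5 and 1), and wtf genes 4 of 16 and 0 (4 and 0). The same counts were, for iron uptake genes, 2 of 11 and 0 (1 and 0), for sugar genes 2 of 12 and 2 (2 and 2), and for phosphate and thiamine genes 1 of 9 and 2 (1 and 2). Lower values numbered 3 of 30 for the proteasome (1), 1 of 15 for glycolysis (1), 1 of 13 for core stress (1; hsp16 at -0.66) and 1 of 12 for chaperones (0), with 0 higher in each. The medians of the chaperone (-0.02), glycolysis (-0.08), meiosis (0.01), sugar (0.01) and wtf (0.06) lists changed sign under at least 1 of the scalings tried. The median and mean of the sugar list were above 0 and its camera direction was down, as was the case for the meiosis list.

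With the replicate as a block, more list members passed in the alp13 deletion. Upstream, lower members then numbered 86 of 110 for subtelomeric, 53 of 119 for meiosis (6 higher), 22 of 44 for centromere-flanking (1 higher), 21 of 30 for proteasome, 11 of 15 for core stress and 8 of 15 for wtf genes. They numbered 7 of 11 for adhesin (1 higher), 5 of 12 for sugar, 3 of 10 for iron uptake and 2 of 13 for S phase genes. In coding regions, higher and lower members numbered 0 and 22 of 54 for ribosomal protein, 2 and 88 of 115 for subtelomeric, 33 and 27 of 112 for meiosis, 13 and 11 of 41 for centromere-flanking and 7 and 1 of 15 for deacetylase complex genes. They were 7 and 2 of 14 for S phase, 6 and 2 of 13 for mating, 6 and 2 of 11 for adhesin, 6 and 1 of 16 for wtf and 5 and 1 of 11 for iron uptake genes. The remaining ones were 1 and 7 of 30 for proteasome, 4 and 1 of 13 for core stress, 2 and 2 of 12 for chaperone, 2 and 2 of 9 for phosphate and thiamine, and 1 and 2 of 15 for glycolysis genes.

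**Figure D3:**
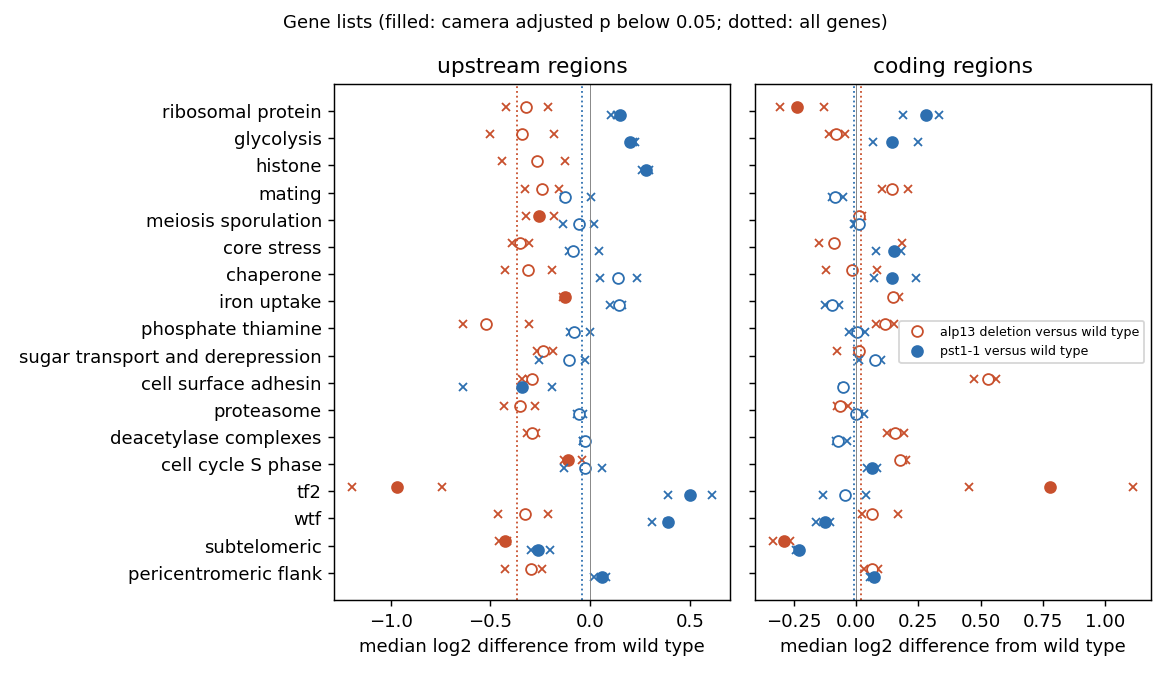
Median log2 difference from wild type of each gene list, upstream and over coding regions. Filled points have a camera adjusted p below 0.05 at the preset correlation, crosses are the scanning days and dotted lines the median of all genes. Tf2 lies at -0.97 upstream and 0.78 in coding regions in the alp13 deletion, and ribosomal protein coding regions lie at -0.24 there and at 0.28 in pst1-1. The medians of chaperone, glycolysis, meiosis, sugar and wtf coding regions in the alp13 deletion, of meiosis, phosphate and proteasome coding regions and of S phase upstream regions in pst1-1 change sign with the scaling.

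Outside protein genes, and relative to the array median, the alp13 deletion had lower H3K9ac at ribosomal RNA genes (-1.02 ± 0.16 SE, limma adjusted p = 3.92e-04, 79 probes) and at the long terminal repeats of retrotransposons (-0.48 ± 0.12, 0.00582, 226 probes). It was also lower in the outermost 100 kb of chromosomes I and II (-0.42 ± 0.11, 0.00750), in the mating-type region (-0.35 ± 0.12, 0.0223) and at snoRNA genes (-0.28 ± 0.11, 0.0387, 58 probes). Centromeric repeats rose by 0.34 ± 0.13 (adjusted p = 0.0311), from -1.97 ± 0.13 to -1.63 ± 0.11, and the sign of that difference turned to -0.19 when arrays were scaled to the same spread. Mitochondrial DNA fell by 0.58 ± 0.13 (0.00365). The sets of ribosomal RNA and tRNA genes can hold mitochondrial probes, whose number was not determined. The difference at ribosomal RNA genes may therefore be partly mitochondrial. Differences at tRNA genes (-0.15, 0.226) and snRNA genes (-0.25, 0.0867; 0.00783 with the replicate block) did not pass. Probes named for the mating-type region that have no match in the reference differed by -0.03 (0.825). All differences that passed had the same sign on both scanning days. Their sizes moved with the scaling. With arrays scaled to the same spread, mitochondrial DNA differed by -1.69, and with background correction the mating-type region differed by -0.75, the outermost 100 kb by -0.75, the long terminal repeats by -0.81 and snoRNA genes by -0.60. The number of called regions was 8, and it was 2 without either wild type replicate and 4 without alp13 deletion replicate 1.

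**Figure D4:**
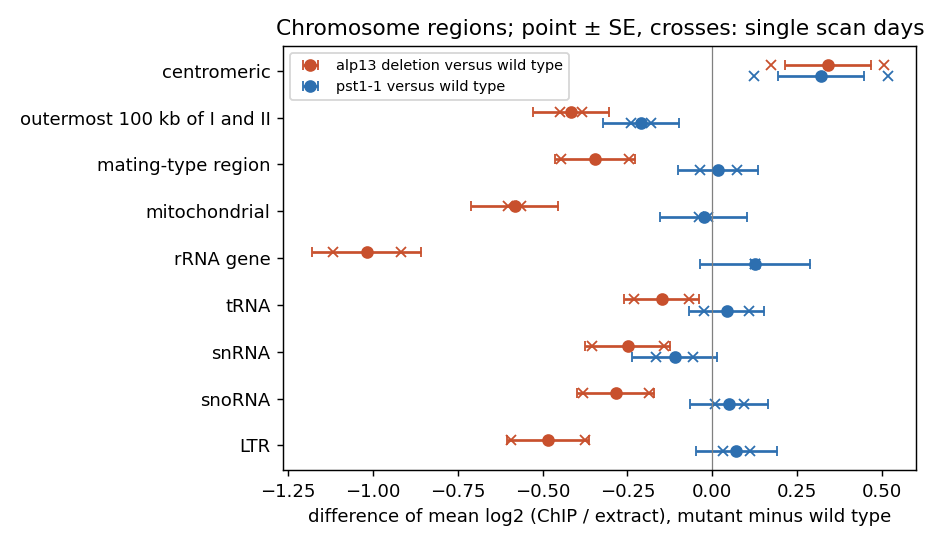
Difference of the mean log2 ratio of ChIP to extract from wild type in chromosome regions, mutant minus wild type. Points are the difference ± SE from limma and crosses the single scanning days. Ribosomal RNA genes stand at -1.02 in the alp13 deletion and at 0.13 in pst1-1, and centromeric repeats at 0.34 and 0.32. The first of these turns to -0.19 with arrays scaled to the same spread.

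The change over coding regions in the alp13 deletion rose with coding length, a relation examined after the values were seen. The median coding difference was -0.20 in 1432 genes with spans under 1000 bp, 0.11 in 832 genes of 1500 to 2000 bp, and 0.42 in 173 genes over 4000 bp. In the shortest class 1.89% of genes rose and 28.3% fell; in the longest 70.5% rose and none fell. Over 4599 genes, not independent replicates, the correlation of the change with log2 coding length was 0.633 (0.619 and 0.622 by scanning day). It was -0.081 for pst1-1 and -0.615 for pst1-1 against the deletion. Lists and named genes were not matched for length. Wild-type coding values fell with length, from a median of 0.19 to -0.36, and in the deletion they were 0.04 and 0.08 in the same classes.

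**Figure D5:**
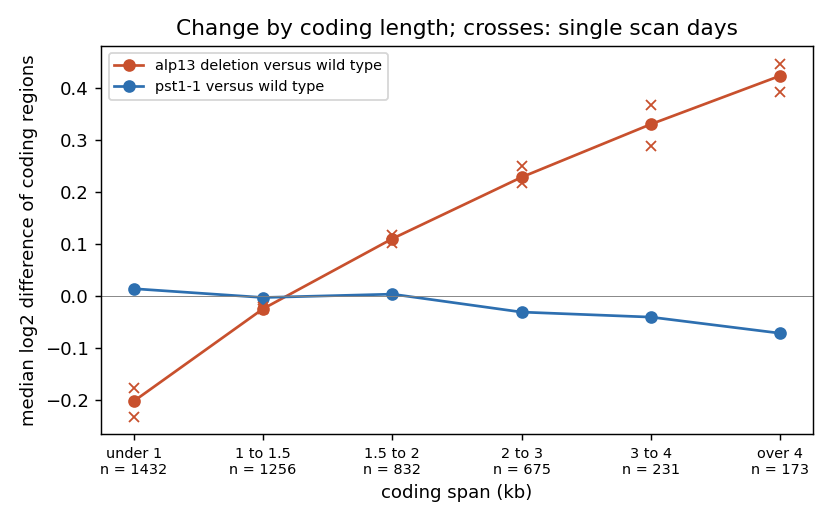
Median log2 difference from wild type of coding regions by coding length in kb, for both mutants. Crosses are the scanning days for the alp13 deletion. The deletion goes from -0.20 in 1432 genes under 1 kb to 0.42 in 173 genes over 4 kb, and pst1-1 from 0.01 to -0.07.

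In pst1-1, few single genes changed. Of 4631 upstream regions 9 rose and 20 fell, and of 4599 coding regions 1 fell and 0 rose. The upstream region shared by the divergent histone genes hht2 (H3, chromosome II, 1365158 to 1365568) and hhf2 (H4) rose from -0.03 ± 0.08 to 0.87 ± 0.17 (n = 2), by 0.90 ± 0.16 (SE; limma adjusted p = 0.00937). Increases upstream were 0.87 at ppe1, a protein phosphatase, 0.83 at cao1, 0.78 at urg1, a uracil-regulated gene, and 0.74 at mrl1; the extract signal of the cao1 coding region was near background in wild type. The largest decrease was at gdt1 (chromosome I, 5540350 to 5541138, near the chromosome end), where the upstream value fell from 0.34 ± 0.26 to -1.32 ± 0.20, by 1.66 ± 0.17 (adjusted p = 2.1e-05), and the coding value by 1.38 ± 0.13 (0.0321). With the marked probes kept, the upstream value at gdt1 was -0.60 and did not pass. Upstream values also fell by 1.17 at plb2, by 1.03 at ght2, a hexose transporter, and by 0.99 at arg82, an inositol polyphosphate kinase.

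Most of these calls rest on 1 or 2 probes and on both pst1-1 arrays. Without pst1-1 replicate 1, the upstream call at gdt1 was the 1 that was left, and its coding value was -1.17. The other values were then 0.78 for hht2, 0.76 for ppe1, 0.64 for cao1, 0.54 for urg1, 0.67 for mrl1, -0.89 for plb2, -0.68 for ght2 and -0.95 for arg82. The call at mrl1 was also lost without pst1-1 replicate 2 (0.81). Changed upstream regions numbered 44 without pst1-1 replicate 2, 47 and 226 without wild type replicate 1 and 2, and 58 without either alp13 deletion array. Changed coding regions numbered 0 without pst1-1 replicate 1 and 2 without wild type replicate 1. No probe passed by limma (3935 at an unadjusted p under 0.05), and in coding regions 657 had an unadjusted p under 0.05. With the replicate block the counts were larger: 934 probes higher and 1251 lower, 139 upstream regions higher and 318 lower, and 188 coding regions higher and 220 lower. The changes correlated between the scanning days at 0.554 over upstream and 0.690 over coding regions. Regions whose arrays did not overlap made up 37.3% upstream and 45.1% in coding sequence, against 33.3% for exchangeable arrays, which leaves the pairing of replicates out of account.

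The profile along genes in pst1-1 differed from wild type by less than it did in the alp13 deletion. The pst1 gene was present in the pst1-1 extract (0.41 ± 0.13 over the array median, against 0.52 ± 0.16 in wild type). How much Pst1 function pst1-1 keeps at 30 C was not measured. The sizes of the changes therefore do not rank complexes I and II. Upstream, pst1-1 stood at 0.22 ± 0.08 (difference -0.04, exact permutation p = 0.667), in the first part of the coding span at 0.06 ± 0.02 (-0.04, p = 0.333) and in the middle at -0.13 ± 0.06 (-0.01, p = 1). The last part stood at -0.10 ± 0.04 (0.03, exact permutation p = 0.667) and downstream at -0.03 ± 0.01 (-0.03, p = 1). The coding minus upstream difference was 0.05 (exact p = 0.667; days 0.10 and 0.01), and by limma 0 genes changed in it (269 at an unadjusted p under 0.05; 77 higher and 36 lower with the replicate block). Clr6 complex genes did not pass: coding differences were -0.06 at clr6, -0.11 at pst1, 0.03 at pst2, -0.01 at alp13 and -0.07 at prw1, and upstream differences were 0.04, -0.02, -0.29, -0.03 and 0.19 in that order.

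With camera at the preset correlation, ribosomal protein and glycolysis genes and Tf2 upstream regions lay higher in pst1-1 and subtelomeric genes lower. None of these calls held with an estimated correlation (adjusted p of 0.262 to 0.801 over all lists called). The median coding difference was 0.28 over 54 ribosomal protein genes, and 96.3% of them were above 0 (median 0.50 with background correction and 0.47 with loess). Of these 0 passed alone over all genes, and 10 rose adjusted over the list alone, among them rps402 (0.60) and rpl803 (0.57). Their upstream median was 0.15 (0.30 with background correction) over 127 genes, of which 0 passed (0 adjusted over the list alone). Glycolysis genes had medians of 0.20 upstream (0 of 15 passed, 0 adjusted over the list alone) and 0.14 in coding regions (0 of 15; 3 rose adjusted over the list alone, among them eno102 at 0.43). Tf2 upstream regions had a median of 0.50, with 0 of 10 passing and 10 rising adjusted over the list alone; the median was 0.22 with background correction, 0.22 with loess and 0.14 with the series table. Subtelomeric genes had medians of -0.26 upstream, where 8 of 110 fell and 1 rose (33 and 5 adjusted over the list alone), and -0.23 in coding regions, where 1 of 115 fell, gdt1 (40 fell and 10 rose adjusted over the list alone).

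Further lists called upstream in pst1-1 were wtf genes (median 0.39, 0 of 15 passing, 5 rising adjusted over the list alone, among them wtf23 at 0.70), histone genes and histone genes (0.28, 2 of 10 rising, hht2 and hhf2; 2). Others were adhesins (-0.34, 0 of 11; 5 lower, among them pfl2 at -0.69) and genes near the centromeres (0.06, 0 of 44; 2 higher and 1 lower). In coding regions the further calls were core stress (0.15, 0 of 13; 0), and chaperones (0.15, 0 of 12; 1 higher, sks2 at 0.57). Calls were also made for S phase genes (0.07, 0 of 14; 3 higher), genes near the centromeres (0.07, 0 of 41; 2 higher) and wtf genes (-0.12, 0 of 16; 1 lower). Camera adjusted p-values at the preset correlation were, upstream, 2.11e-10 for Tf2, 2.19e-10 for wtf, 2.5e-09 for ribosomal protein and 5.21e-08 for subtelomeric genes. They were 2.69e-06 for histone, 5.15e-04 for glycolysis and for adhesin, and 0.0068 for centromere-flanking genes. In coding regions they were 2.14e-17 for ribosomal protein, 1.31e-08 for subtelomeric, 4.64e-04 for glycolysis, 0.00703 for wtf and for centromere-flanking genes. The others were 0.0152 for chaperone, 0.0226 for core stress and 0.0434 for S phase genes (0.0699 with the replicate block). No list was called with an estimated correlation. The adjusted p was then 0.262 for subtelomeric, 0.396 for Tf2, wtf, histone and adhesin and 0.544 for glycolysis genes. It was 0.589 for ribosomal protein and 0.671 for centromere-flanking genes upstream, and 0.756 to 0.801 for the lists called in coding regions. By fry no list was called either (smallest adjusted p 0.0763, subtelomeric genes upstream).

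Single members of the lists passed in pst1-1 with the replicate block. Higher and lower members upstream then numbered 7 and 42 of 110 for subtelomeric, 10 and 0 of 10 for Tf2, 9 and 0 of 127 for ribosomal protein, 8 and 0 of 15 for wtf, 4 and 0 of 10 for histone and 3 and 0 of 15 for glycolysis genes. They were 4 and 2 of 44 for centromere-flanking, 2 and 5 of 119 for meiosis, 0 and 5 of 11 for adhesin, 0 and 3 of 15 for core stress and 1 and 3 of 30 for proteasome genes. For mating genes they were 1 and 2 of 14, for iron uptake 2 and 1 of 10, for sugar 0 and 2 of 12, for chaperone 1 and 0 of 11 and for deacetylase complex genes 0 and 1 of 14. In coding regions they were 10 and 55 of 115 for subtelomeric, 15 and 0 of 54 for ribosomal protein, 7 and 7 of 112 for meiosis, 5 and 0 of 15 for glycolysis and 4 and 0 of 41 for centromere-flanking genes. They were 3 and 0 of 30 for proteasome, 3 and 0 of 14 for S phase, 0 and 3 of 16 for wtf, 0 and 2 of 13 for mating and 2 and 0 of 12 for sugar genes. The last were 1 and 1 of 11 for adhesin, 1 and 0 of 12 for chaperone, 0 and 1 of 11 for iron uptake and 0 and 1 of 9 for phosphate and thiamine genes.

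Lists that were not called in pst1-1 by camera had upstream adjusted p-values of 0.0616 for chaperone, 0.135 for sugar (1 of 12 fell, ght2; 1 adjusted over the list alone), and 0.212 for iron uptake (0 of 10; 1 lower, fep1 at -0.68). They were 0.474 for mating (0 of 14; 0), 0.484 for core stress (0 of 15; 0) and 0.858 for deacetylase complex (0 of 14; 1 lower, clr3 at -0.68). The largest were 0.941 for proteasome (0 of 30; 0) and for phosphate and thiamine (0 of 9; 0), and 0.986 for meiosis (0 of 119; 0) and S phase genes (0 of 13; 0). No chaperone passed (0 of 11; 0). In coding regions the adjusted p was 0.186 for mating (0 of 13; 0), 0.277 for iron uptake (0 of 11; 0), 0.317 for sugar (0 of 12; 1 higher, ght4 at 0.35), and 0.329 for proteasome (0 of 30; 1 higher, pre5 at 0.44). It was 0.466 for adhesin (0 of 11; 1 lower, pfl9 at -0.59), and 0.541 for deacetylase complex (0 of 15; 0), and 0.636 for phosphate and thiamine (0 of 9; 0), 0.727 for Tf2 (0 of 13; 0) and 0.938 for meiosis genes (0 of 112; 0). The medians of the meiosis (0.01), phosphate and thiamine (0.00) and proteasome (-0.00) coding regions and of S phase upstream regions (-0.03) changed sign under at least 1 scaling, and the first 3 of these had means of the other sign.

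Among chromosome regions, none passed in pst1-1 by limma without the block (1 at an unadjusted p under 0.05). Centromeric repeats differed by 0.32 ± 0.13 (adjusted p = 0.293; 0.0093 with the replicate block, where the region is called), with 0.12 and 0.52 on the scanning days. The outermost 100 kb differed by -0.21 ± 0.11 (0.462), ribosomal RNA genes by 0.13 (0.885) and the long terminal repeats by 0.07. The differences were 0.05 at snoRNA genes, 0.04 at tRNA genes, 0.02 in the mating-type region, -0.03 in mitochondrial DNA, -0.11 at snRNA genes and -0.04 at the unmatched mating-type probes, each, like the repeats, with an adjusted p of 0.885.

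Compared directly, and relative to the array median, pst1-1 had more H3K9ac upstream of genes than the alp13 deletion and less over many coding regions. Upstream, 1690 genes were higher in pst1-1 and 61 lower, and in coding regions 719 were higher and 1013 lower. The coding minus upstream difference was lower by 0.33 (exact permutation p = 0.333, the smallest possible; n = 2 and 2), with 1175 genes lower and 16 higher by limma (2117 and 88 with the replicate block). The largest upstream difference was at met9, an enzyme of the methyl cycle (chromosome I, 1143115 to 1144926), with 1.85 ± 0.03 in pst1-1 and 0.05 ± 0.37 in the deletion, a difference of 1.80 ± 0.18 (SE; adjusted p = 1.37e-05). Next were the shared region of wtf13 and the importin gene nmd5 (1.72), 4 Tf2 copies (Tf2-2, Tf2-4, Tf2-9 and Tf2-13, 1.57 each); the Tf2 probes match several places. Lower upstream values in pst1-1 were found at pat1 (-0.93), msa1, a repressor of sexual differentiation (-0.84), lsd90 (-0.83) and gdt1 (-0.81). With the marked probes kept, the gdt1 difference had the opposite sign (0.48), and without pst1-1 replicate 1 it did not pass (-0.67), nor did msa1 (-0.52) or lsd90 (-0.72). The value of lsd90 was -0.28, not passing, without alp13 deletion replicate 1 and -1.38 without alp13 deletion replicate 2.

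In coding regions pst1-1 exceeded the deletion most at ubi4, the polyubiquitin gene (chromosome II, 1044418 to 1045566), with -0.39 ± 0.07 against -1.78 ± 0.17 (n = 2), a difference of 1.39 ± 0.16 (limma adjusted p = 0.00441), although some of its probes match several places. Further higher values were at meu10, a spore wall gene (1.20), mug155 (1.08) and mrpl16, a mitochondrial ribosomal protein (1.06). These were followed by mug153 (1.01), ecm31, an enzyme of pantothenate synthesis (1.01), spd1, the inhibitor of ribonucleotide reductase (0.95), and tim15 (0.95). Values were lower in pst1-1 at gsf2 (-1.21), cts2, a chitinase (-1.07), fml1 (-1.07) and mam3, an agglutinin (-1.07). Coding values of pst1 (-0.51), clr6 (-0.43), pst2 (-0.32) and prw1 (-0.27) were lower in pst1-1, and upstream values of pst1 (0.64) and prw1 (0.59) higher. Upstream values of clr6 (0.16) and pst2 (-0.08) did not pass. The alp13 gene was higher in pst1-1 in coding (0.48) and upstream (0.74) values; the coding extract of the deletion was at background. Many of these calls did not hold without pst1-1 replicate 1: values were then 0.87 for mug155, 0.85 for mrpl16, 0.79 for ecm31, 0.54 for tim15, -0.85 for gsf2, -0.74 for cts2 and -0.69 for mam3. Coding values were then -0.37 for pst1, -0.40 for clr6, -0.31 for pst2, -0.22 for prw1 and 0.42 for alp13, and upstream values 0.55 for pst1 and 0.47 for prw1, all not passing. Calls were also lost without alp13 deletion replicate 2 for mam3 (-0.77), pst1 upstream (0.50), pst2 (-0.33) and prw1 (-0.27, and 0.57 upstream). Without alp13 deletion replicate 1 they were lost for pst2 (-0.30) and prw1 (-0.28, and 0.60 upstream), and without pst1-1 replicate 2 for pst2 (-0.32).

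Ribosomal protein coding regions stood higher in pst1-1 than in the deletion in 43 of 54 genes (44 adjusted over the list alone; median 0.52), and upstream in 68 of 127 (79; median 0.44). Glycolysis genes were higher in 10 of 15 upstream (10) and in 6 of 15 coding regions (6), and histone genes in 8 of 10 upstream (8). Higher upstream values were also found in 13 of 15 wtf genes (13) and in 10 of 10 Tf2 copies (10), while 13 of 13 Tf2 coding regions were lower (13). The coding value of Tf2-2, Tf2-4 and Tf2-9, -0.85, did not pass without pst1-1 replicate 1 (-0.90) or 2 (-0.80), and was -0.49 without alp13 deletion replicate 2. Subtelomeric coding regions were higher in 29 of 115 and lower in 4 (29 and 3). Camera adjusted p-values in coding regions were 4.45e-16 for ribosomal protein, 1.67e-04 for Tf2, 0.00238 for subtelomeric and 0.00703 for glycolysis genes, with 0.825 for each under an estimated correlation. Upstream, lists above the other genes had camera adjusted p-values of 8.82e-13 for Tf2, 3.47e-04 for wtf, 0.00136 for ribosomal protein, 0.00294 for histone and 0.0216 for glycolysis genes, with 0.468, 0.563, 0.670, 0.563 and 0.571 under an estimated correlation.

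Lists below the other genes upstream, whose median was 0.32, were adhesins (median -0.01, sign changing with the scaling), with 1 of 11 higher and 2 lower (1 and 2 adjusted over the list alone). Also below the other genes were sugar genes (1 of 12 higher; 1), mating genes (2 of 14 higher and 1 lower; 2 and 1), S phase genes (0 of 13; 0), meiosis genes (31 of 119 higher and 6 lower; 30 and 6) and subtelomeric genes (36 of 110 higher and 5 lower; 36 and 5). Their camera adjusted p-values were 5.65e-04, 0.0117, 0.0157, 0.0239, 0.00294 and 0.0157 in that order, and 0.468, 0.563, 0.468, 0.571, 0.571 and 0.468 under an estimated correlation. The subtelomeric call was lost with the replicate block (0.105). The other upstream lists were not called (adjusted p of 0.179 to 0.784). Core stress had 3 of 15 higher (3), chaperones 6 of 11 (6), and phosphate and thiamine genes 3 of 9 and 1 lower (3 and 1). The proteasome list had 11 of 30 higher (12), deacetylase complex 5 of 14 (5, and 1 lower), iron uptake 2 of 10 and 1 lower (1 and 1), and genes near the centromeres 23 of 44 and 1 lower (27 and 1). The other coding lists were not called either (adjusted p of 0.0530 or more). Higher and lower members numbered 0 and 6 of 16 for wtf (0 and 6), 1 and 6 of 11 for adhesin (1 and 7), 2 and 7 of 15 for deacetylase complex (3 and 8), 3 and 5 of 14 for S phase (3 and 5), and 2 and 5 of 13 for mating (2 and 5). They numbered 22 and 23 of 112 for meiosis (23 and 24), 6 and 8 of 41 for centromere-flanking (6 and 8), 6 and 0 of 30 for proteasome (2 and 0), and 3 and 0 of 12 for chaperone (1 and 0). In the last lists they were 3 and 1 of 13 for core stress (3 and 1), 0 and 3 of 11 for iron uptake (0 and 3), 1 and 2 of 9 for phosphate and thiamine (1 and 2) and 2 and 2 of 12 for sugar genes (2 and 2). By fry the deacetylase complex list was lower on balance in coding regions (adjusted p = 0.00257). Upstream, fry called 12 lists as higher on balance: ribosomal protein, histone, chaperone, proteasome, Tf2, wtf and subtelomeric genes (adjusted p of 0.0359 each), iron uptake (0.0384), and glycolysis, core stress, deacetylase complex and centromere-flanking genes (0.0423 each).

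Fitted with the replicate block, higher and lower members upstream in pst1-1 against the deletion numbered 53 and 13 of 110 for subtelomeric, 51 and 10 of 119 for meiosis, 29 and 2 of 44 for centromere-flanking, 19 and 0 of 30 for proteasome and 9 and 1 of 15 for core stress genes. They were 8 and 1 of 14 for deacetylase complex, 6 and 1 of 9 for phosphate and thiamine, 4 and 1 of 10 for iron uptake, 3 and 2 of 14 for mating, 3 and 2 of 11 for adhesin, 2 and 1 of 12 for sugar and 2 and 0 of 13 for S phase genes. In coding regions they were 39 and 18 of 115 for subtelomeric, 26 and 38 of 112 for meiosis, 13 and 9 of 41 for centromere-flanking, 11 and 2 of 15 for glycolysis, 7 and 2 of 13 for core stress and 7 and 1 of 30 for proteasome genes. For chaperone genes they were 5 and 1 of 12, for S phase 5 and 5 of 14, for adhesin 3 and 7 of 11, for phosphate and thiamine 2 and 2 of 9 and for wtf genes 1 and 8 of 16.

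Of the chromosome regions, ribosomal RNA genes (1.14 ± 0.16 SE, limma adjusted p = 1.25e-04), mitochondrial DNA (0.56, 0.00346), long terminal repeats (0.56, 0.00305), the mating-type region (0.36, 0.0254) and snoRNA genes (0.33, 0.0275) were higher in pst1-1 than in the deletion. With arrays scaled to the same spread the mitochondrial difference was 1.58, and with background correction those of the mating-type region and snoRNA genes were 0.81 and 0.73. The outermost 100 kb (0.21, 0.136; 0.0316 with the replicate block), tRNA genes (0.19, 0.154; 0.0418 with the block), snRNA genes (0.14, 0.359), unmatched mating-type probes (-0.01, 0.942, sign changing with the scaling) and centromeric repeats (-0.02, 0.942, and 0.46 with arrays scaled to the same spread) did not pass. By probe, 6210 were higher and 5648 lower in pst1-1 (10872 and 9156 with the replicate block). The blocked counts were 2556 higher and 126 lower upstream and 1217 higher and 1506 lower in coding regions. Without pst1-1 replicate 1 the changed probes, upstream regions and coding regions numbered 58, 254 and 67. Without alp13 deletion replicate 1 they numbered 4187, 976 and 985. Without alp13 deletion replicate 2 the changed probes and upstream regions numbered 4817 and 801. Called regions numbered 6, counting the pNSU probes without a match, and 3 without alp13 deletion replicate 1 or without pst1-1 replicate 2.

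The changes in both mutants correlated at 0.164 over 38797 probes, 0.236 over upstream and 0.0883 over coding regions. The shared wild-type arrays alone gave 0.50 for each in simulations, so these cannot show relatedness. Mutant arrays of different days, each set against wild type of its day, share no array. Correlations were then 0.0275 and 0.114 over probes, 0.137 and 0.146 upstream and 0.0676 and 0.0458 over coding regions. Leaving out single arrays moved the correlation over probes from -0.0674 (without pst1-1 replicate 2) to 0.494 (without wild type replicate 2). Values were -0.0404 without wild type replicate 1, 0.226 and 0.0835 without alp13 deletion replicates 1 and 2, and 0.398 without pst1-1 replicate 1. With the replicate block, 114 coding regions fell in both mutants where independent lists of the same sizes would share 51.8, and 51 rose in both against 56.2. Upstream, 251 fell in both against 196, and 4 rose in both against 1.35. Both comparisons use the same wild-type arrays, so shared calls are not independent.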

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

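Of the tests in this part, that of weaker enrichment was chosen only after the result was seen, as were the values by scanning day. Those of the extract channel and of coding length were written before their results.

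The mutants changed H3K9ac differently at many genes. Tested directly with limma, pst1-1 and the alp13 deletion differed at 1751 upstream regions and at 1732 coding regions, and this difference between the groups is what marked the result for a closer look. The results in the next 2 paragraphs come from data outside the main comparisons: the extract channel alone, and probes without a place in the reference.

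Some genes had little or no DNA in the extract of some strains, besides alp13 in its own deletion. For cbm1 and cao1, neighbouring genes on chromosome I, the extract signal was 1.05 to 1.12 times the local background on the wild-type arrays. In the alp13 deletion it was 5.21 and 2.64 times the background for cbm1 and 4.42 and 2.33 for cao1, and in pst1-1 5.14 and 2.70, and 4.49 and 2.58. The extract signal relative to the array median was thereby higher in the alp13 deletion than in wild type by 2.05 for cbm1 and 1.76 for cao1 (limma adjusted p of 0.0193 for each, higher on 2 of 2 arrays). For ura4 the extract signal was 1.17 times the background on both arrays of the alp13 deletion, against 4.10 and 1.98 in wild type and 3.93 and 2.27 in pst1-1, a difference from wild type of -1.15 (lower on 2 of 2 arrays) that limma did not call. Ratios of ChIP to extract over these coding regions in those strains are ratios of background signals, and the upstream increases named for cao1 in both mutants lie next to such a region. The strains thus differed in extract signal at loci other than alp13 and pst1. Effects of such strain differences cannot be told apart from those of the named mutations in comparisons with wild type. Across 4599 coding regions, limma called 6 extract signals higher and 1 lower in the alp13 deletion (117 at an unadjusted p under 0.05), 2 higher in pst1-1 (118) and none between the mutants (110). With the replicate block, 27 were higher and 17 lower in the deletion, 35 and 7 in pst1-1, and 31 and 5 in pst1-1 against the deletion.

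The 54 probes named pNSU, which have no match in the reference, had a lower ratio of ChIP to extract in the alp13 deletion than in wild type (-0.47 ± 0.14 SE, limma adjusted p = 0.0147, lower on both scanning days). The difference was -0.10 in pst1-1 (adjusted p = 0.885), and pst1-1 exceeded the deletion by 0.37 (0.0462). With arrays scaled to the same spread the difference for the deletion was -1.23 and that between the mutants was larger as well, so their size depends on the scaling. What sequence these probes stand for could not be read from the files used here.

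The first pattern weighed was the fall of upstream relative to coding H3K9ac in the alp13 deletion. Weaker enrichment of the precipitated DNA would keep the order of genes and bring mitochondrial probes closer to the median, but the correlation of the group means over coding regions, corrected for the replicates, was 0.653 (0.927 for pst1-1), and mitochondrial probes moved by -0.58 ± 0.13 (SE), away from the median. The extract channel made up 6.24% of the coding minus upstream change (-0.02 against 0.36 in the ChIP channel), which argues against the extract channel as its whole cause. The change was 0.33 on the scanning day with the smaller value. Each group had 1 array on each day, so a day effect shared by the groups cancels from the difference, and the values by day do not test it. A loss of Alp13 function, the difference between strains that the design names, stays open as a hypothesis, untested beyond these explanations. It cannot be told apart from other differences between these strains, such as those in extract signal at cbm1, cao1 and ura4. Upstream and coding regions also differ in their wild-type level, and how far the change follows that level rather than position was not separated.

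The second pattern was the higher level of ribosomal protein coding regions in pst1-1, a median shift of 0.29 relative to the other genes, positive in 96.3% of 54 genes. The extract channel made up 0.242% of the shift, which argues against the extract channel as its cause. The shift was 0.33 and 0.21 on the scanning days. With each group on both days, a day effect shared by the groups cancels, and these values do not test it. The list is not called when camera estimates the correlation between genes (adjusted p = 0.756), so whether it moves by more than its members' joint scatter stays open. An effect of the pst1-1 mutation may underlie the shift and was not tested apart from the explanations above. It cannot be told apart from other differences between these strains, such as those in extract signal at cbm1 and cao1.

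The third pattern was the increase of the coding change with coding length in the alp13 deletion. The change was taken at 500 to 900 bp from the start codon and at least 500 bp from the stop codon. It was 0.24 in 362 genes of at least 3000 bp and 0.14 in 986 genes of 1400 to 2000 bp. The difference was 0.10 ± 0.02 (SE). This SE is over genes, which are not independent replicates, and leaves out the spread between arrays. Medians over whole coding regions lay further apart, at 0.11 for 1500 to 2000 bp and 0.33 for 3000 to 4000 bp. Part of the relation may thus go with distance from the gene ends. The distance to the stop codon was not matched, so the 0.10 may do so too. With 1 probe drawn from each of 4960 genes the correlation with log2 length was 0.575, which argues against the number of probes averaged as the whole cause. A role of Alp13 along long transcribed genes may explain the relation and was not tested, and long genes also had lower wild-type values, which leaves the wild-type level open as well.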

How the results depend on the processing

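Background correction combined with the replicate block, and leaving out probes with low extract signal, were chosen only after the data were seen; the other alternatives were fixed before. Counts are of limma calls at an adjusted p below 0.05 unless stated, the cause of a change was not tested unless given, and the values to compare with are those of the report.

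The coding minus upstream gain in the alp13 deletion was positive under every alternative, from 0.28 to 0.74, and the wild-type excess of upstream over coding values was positive from 0.15 to 0.43. Keeping only probes well above background, leaving out probes with low extract signal and the 300 bp upstream window moved no count by more than 1.5 times and no value by more than the spread between replicates. Of the values of named genes under the alternatives, 7993 stayed on the same side of the threshold with the same direction, 426 no longer passed, 479 passed where they had not, 25 changed sign without a call and 1 changed sign with a call.

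With background-corrected signals (normexp), changed probes numbered 17705 in the alp13 deletion, 314 in pst1-1 and 18892 between the mutants. Upstream regions numbered 86 in pst1-1 and 2788 between the mutants, and coding regions 2435 in the deletion, 397 in pst1-1 and 2695 between the mutants. Genes with a changed coding minus upstream difference numbered 2293 in the deletion and 3 in pst1-1, the mean of that difference in the deletion was 0.74, upstream lists called there numbered 1, and the wild-type excess was 0.43.

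With the series table's values, changed probes numbered 18192 in the deletion, 250 in pst1-1 and 19202 between the mutants, and upstream regions 85 in pst1-1 and 2798 between the mutants. Coding regions numbered 2220 in the deletion and 83 in pst1-1, genes with a changed coding minus upstream difference 2270 and 4, upstream lists in the deletion 2 and coding lists between the mutants 7. The correlation of the changes in both mutants was 0.0943 over probes.

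With the replicate block, probes numbered 19336 in the deletion, 2185 in pst1-1 and 20028 between the mutants. Upstream regions numbered 457 in pst1-1 and 2682 between the mutants, and coding regions 2457, 408 and 2723 in the order of the probes. Genes with a changed coding minus upstream difference numbered 2525 and 113, and 1 chromosome region was called in pst1-1, the centromeric repeats. Background correction together with the block gave 23198, 5786 and 24096 probes, 3442, 867 and 3334 upstream regions, and 3095, 1357 and 3265 coding regions. It gave 2932 and 386 genes with a changed coding minus upstream difference, 1 upstream list in the deletion, 5 coding lists in pst1-1 and 1 chromosome region in pst1-1. The block takes the scanning day out of the residual spread, and it equals the replicate number, so no separate fit of the day could be made.

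With loess within arrays, upstream lists in the deletion numbered 2, its coding minus upstream change was 0.65, the wild-type excess was 0.42, and pst1-1 had 104 coding regions and 1 chromosome region. With arrays scaled to the same spread, upstream lists numbered 3 in the deletion and 7 between the mutants, coding lists in pst1-1 4, changed probes in pst1-1 1, and the correlation of the changes was 0.101. With the marked probes kept, upstream lists in the deletion numbered 3, and the upstream difference between the mutants at gdt1 turned to 0.48, which is the change of sign with a call. With a trended and robust prior, upstream lists in the deletion numbered 3, and in pst1-1 there were 22 probes, 138 upstream regions and 11 genes with a changed coding minus upstream difference. With only the 4 arrays of both groups, pst1-1 had 58 upstream regions and 11 such genes.

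Without upstream probes shared by divergent genes, upstream lists numbered 1 in the deletion, 4 in pst1-1 and 5 between the mutants, and fewer genes were tested. Without probes of several places, they numbered 2 in the deletion, and coding lists 5 in pst1-1. With at least 4 probes per coding region, limma called 0 coding regions in pst1-1 (455 at an unadjusted p under 0.05). Camera with an estimated correlation called 0 lists in each comparison, upstream and in coding regions. At an unadjusted p under 0.05 it gave 1 list upstream in pst1-1 and 0 in the others, and at the preset correlation the lists called upstream and in coding regions numbered 5 and 3 in the deletion, 8 and 8 in pst1-1 and 11 and 4 between the mutants.

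Leaving out each array in turn leaves a group with a lone array, which is assumed to vary like the other groups. In the alp13 deletion the lowest and highest counts were 1237 and 12264 probes, 693 and 2308 upstream regions, 4 and 5 upstream lists, 223 and 1246 coding regions, 3 and 5 coding lists, and 2 and 7 chromosome regions. Genes with a changed coding minus upstream difference numbered 293 to 2144, and its mean was 0.28 to 0.49. In pst1-1 the ranges were 0 to 9 probes (by limma; 3419 at an unadjusted p under 0.05 without either alp13 deletion array), 1 to 226 upstream regions, 8 to 10 upstream lists, 0 to 2 coding regions (309 unadjusted without pst1-1 replicate 1) and 6 to 8 coding lists. Called chromosome regions numbered 0 each time (at most 1 unadjusted), genes with a changed coding minus upstream difference 0 to 32 (269 unadjusted with all arrays, where none is called), and its mean was -0.05 to 0.16. Between the mutants the ranges were 58 to 13874 probes, 254 to 2052 upstream regions, 7 to 10 upstream lists, 67 to 1791 coding regions, 3 to 7 coding lists and 3 to 5 chromosome regions. The wild-type excess was 0.15 to 0.36, and the extract signal over alp13 in the deletion -2.31 to -1.49 relative to wild type. The correlation of the changes in both mutants was -0.0674 to 0.494, and below 0 without pst1-1 replicate 2 or wild type replicate 1.

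Signal over background limits the measurement at weak probes. The local background made up 18.5% to 39.0% of the median Cy3 signal, and the processed signals have no background subtracted, so ratios far from 0 are drawn towards 0 by an amount not determined here. With background correction the coding minus upstream change of the deletion was 0.74 against 0.38.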

Other observations

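All values in this part were chosen only after they were seen, and no further tests were run on them.

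In pst1-1, several of the upstream regions with lower H3K9ac lie at the right end of chromosome I. Of the 20 upstream regions that fell in pst1-1, 8 lie among the 32 genes measured in the outermost 100 kb of that end, between positions 5529962 and 5556768. The differences were -0.72 at SPAC186.02C, -0.76 at SPAC186.03, -1.36 at SPAC186.04C, -1.66 at gdt1, -1.31 at SPAC186.06, -1.18 at SPAC186.07C, -1.04 at SPAC186.08C and -1.16 at SPAC750.01 (limma adjusted p of 2.1e-05 to 0.0372, each lower on both scanning days). These calls rest on both pst1-1 arrays: without pst1-1 replicate 1 the call at gdt1 was the 1 left among all upstream regions, and with the marked probes kept gdt1 stood at -0.60 and did not pass. In the alp13 deletion the same regions differed by -0.39, -0.34, -0.54, -0.85, -0.33, -0.66, -0.57 and -0.46. The extract signal of these upstream regions changed by -0.12 to 0.14 in pst1-1.

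The other chromosome ends had few or no calls in pst1-1. Limma called 0 of 26 upstream regions at the left end of I and 0 of 28 at the left end of II, and 1 of 24 rose at the right end of II. At an unadjusted p under 0.05 there were 14, 14 and 12 at these ends and 18 at the right end of I, so the ends differ less than the adjusted calls do. The median upstream difference in pst1-1 was -0.32 at the left and -0.39 at the right end of I, and -0.26 and -0.18 at the ends of II. In the alp13 deletion the medians were -0.51, -0.42, -0.40 and -0.34, with 18, 13, 12 and 8 regions lower.

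The extract signal of pho1 was higher in pst1-1 than in wild type by 0.81 (limma adjusted p = 0.0355, higher on 2 of 2 arrays). It stood at -0.27 and -0.18 in pst1-1, at -0.49 and -0.47 in the alp13 deletion and at -1.08 and -0.99 in wild type, so both mutants had higher values.

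Changes in the alp13 deletion were related to the wild-type level when level and change were taken from arrays of different scanning days. The correlations over genes were -0.49 and -0.59 for upstream and -0.51 and -0.59 for coding regions.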
